A study of Homo sapiens with 18 samples.

How the data were processed

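RNA was sequenced from NCI-H292 cells with wild type MET or the exon 14 skipped form, at 0, 6 and 24 h of HGF, with 3 libraries in each of 6 groups. The deposited files hold raw counts per gene, 1 library per file, with no normalization. The authors' processing notes name STAR 2.6.1b, HTSeq 0.6.1 and the build GRCh38 without saying what each was used for, and give neither the annotation release nor the strand setting. The extract protocol names both a QuantSeq 3' mRNA kit and a DNBseq RNA-seq protocol, so it is open whether reads come from transcript ends or whole transcripts, and no length-scaled values were computed.

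Each file had 58929 gene rows and 5 closing rows for reads given to no gene. The 45 rows for the copy of the pseudoautosomal genes on chromosome Y, which held 13 reads in all, were left out, and 58884 gene identifiers were used. Symbols came from a separate table of gene names, which paired 58472 identifiers with a symbol, and positions and gene types came from GENCODE 29. Gene counts summed to between 37948690 and 40651214 per library. The spread between libraries, with a common biological coefficient of variation of 6.12%, rather than counting error limits the precision for genes well above the floor. The chi-square per gene between libraries of a group lay between 3.85 and 14.5, so no library was a duplicate of another.

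Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with its default settings by group, which left 16596, and libraries were scaled by TMM. A model with 1 mean for each of the 6 groups was fitted to all 18 libraries (12 residual degrees of freedom) with robust quasi-likelihood dispersions. The 9 comparisons were MET-D14Ex against wild type at each time, HGF against 0 h at 6 and 24 h in each genotype, and the difference between the genotypes in the HGF response at 6 and 24 h. The edgeR quasi-likelihood test was two-sided, p was adjusted by Benjamini-Hochberg within each comparison, and the threshold was 0.05. Counts of genes changed at least 2-fold add a limit of 1 on the absolute log2 fold change. CPM were computed with the TMM factors.

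Gene sets were 38 lists written down before the data were examined, with 940 members of which 864 were tested. They were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, giving 342 tests adjusted within each comparison. Camera with an estimated correlation and fry were the alternatives. Calls named in the report hold with an estimated correlation unless the text gives that p.

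The named genes were set by a rule written before the data were examined. It takes MET, in each comparison the 6 higher and 6 lower genes with the largest log2 fold change among those past the test with a symbol, at least 10 CPM in the highest group and, between 2 groups, libraries that do not overlap. It also takes from each list described up to 4 members past the test with the largest change and up to 2 members not past it with the highest level, and a fixed panel of signalling, protease and adhesion genes. A choice among the members that the rule gives was made for length, and some genes that the rule gives are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

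The size of the HGF response was compared over genes whose mean response of both genotypes passed the test at 2-fold or more. An exact two-sided permutation test used 1 score per HGF library, taken from the 0 h mean of its genotype. The alternatives were size factors from DESeq2 and upper-quartile factors in edgeR, no filter beyond 1 count, a filter of at least 5 CPM in 3 libraries, DESeq2 1.42.0, only the libraries of the groups compared, the replicate number as a block, and each library left out in turn.

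A scan for runs of neighbouring genes, added after the data were seen, used the 10097 protein-coding genes on the 22 autosomes with a mean of at least 5 CPM. It took each gene's log2 difference between the genotypes at 0 h, limited to 1 in size and less an offset of 0.4, and found the stretches with the highest sum, against 1000 shuffles of the gene order. It used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

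The procedure was tested on simulated data, negative binomial counts drawn with the mean profile of the wild type 0 h libraries, the measured library sizes and the fitted dispersion of each gene. Between the genotypes at 0 h, 93 of 100 genes changed 2-fold and 83 of 100 changed 1.5-fold were called, with 12 false among 188 calls (6.38%). At 24 h these were 92 of 100 and 89 of 100, with 14 false among 195 calls (7.18%), and for the 24 h difference 174 of 200 and 155 of 200, with 21 false among 350 calls (6.0%). A list of 22 genes raised 1.3-fold was called and 0 of 37 other lists were. Genes were drawn independently of each other, so this does not show how often lists of correlated genes are called falsely. Only a small part of the 15919 simulated genes was changed in single genes, with random signs. In the measured data 57.2% of genes were called between the genotypes at 24 h. Scaling and false calls where most genes change were therefore not tested. A simulated run of 30 genes lowered by 0.8 on the log2 scale was found with all 30 genes.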

Results

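Gene expression was measured by RNA sequencing in NCI-H292, an established lung mucoepidermoid carcinoma cell line, to ask which pathways differ in cells with the exon 14 skipped form of MET. MET is the receptor tyrosine kinase for hepatocyte growth factor (HGF), and the skipped exon encodes part of the segment just inside the membrane, which holds the binding site for the ubiquitin ligase CBL. Libraries came from cells labelled wild type and from cells labelled with the skipped form, called MET-D14Ex here. Both were kept in serum-free medium for 18 h and then given HGF at 100 ng/mL for 0, 6 or 24 h, with 3 libraries in each of the 6 groups. Gene counts summed to between 37948690 and 40651214 per library, and 16596 genes were tested. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which can be technical. They also do not say how the MET-D14Ex cells were made or how many clones they stand for. No library without HGF was analysed at 6 or 24 h, so every comparison with 0 h covers HGF and time in culture together. Below, levels are CPM (counts scaled to the library total times its TMM factor) as mean ± SD over n = 3 libraries, and log2 fold changes stand with ± their standard error. A gene is called changed when its adjusted p in edgeR's quasi-likelihood test was under 0.05. The largest changes are ranked among changed genes with a symbol and at least 10 CPM in the highest group compared. Between 2 groups their libraries also do not overlap. Where no other pair of counts is given for a gene list, the counts adjusted over the list alone were the same.

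MET itself (ENSG00000105976.15, chromosome 7, 116672390 to 116798386 on the plus strand of GRCh38, GENCODE 29) was abundant in all 18 libraries. In wild type cells it stood at 374 ± 13.7 CPM at 0 h, 384 ± 20.9 CPM at 6 h and 369 ± 20.03 CPM at 24 h. In MET-D14Ex cells it stood at 426 ± 15.5 CPM at 0 h, 335 ± 2.46 CPM at 6 h and 681 ± 45.5 CPM at 24 h. The log2 fold change of MET-D14Ex against wild type was 0.19 ± 0.05 at 0 h, -0.19 ± 0.05 at 6 h and 0.88 ± 0.05 at 24 h. The adjusted p of edgeR for MET was 0.00351, 0.00235 and 6.27e-18. Counts per gene do not separate transcripts with and without exon 14, so these values check the level of MET and not the genotype.

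**Figure D1:**
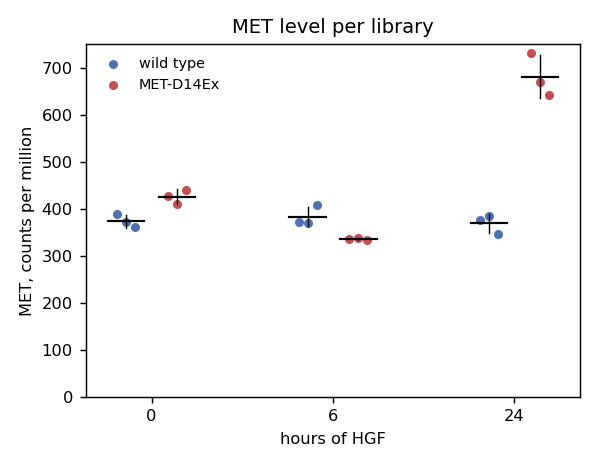
MET level in CPM (y axis) in each of the 18 libraries by hours of HGF (x axis). Points are libraries, horizontal bars group means and vertical bars 1 SD. The 3 MET-D14Ex libraries at 24 h lie above all others, with a mean of 681 CPM.

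Before HGF, MET-D14Ex and wild type cells differed in stress, cell cycle, cytokine and signalling genes. Targets of NRF2, the transcription factor of the oxidative stress response, were higher in MET-D14Ex cells, with 22 of 25 measured members higher and 0 lower (camera adjusted p = 3.7e-20). Among them AKR1C3, an aldo-keto reductase, stood at 51.2 ± 1.40 against 22.6 ± 1.19 CPM, and ABCC2, an efflux pump, at 4.19 ± 0.568 against 1.06 ± 0.213 CPM. AKR1C3 lies in a run of higher neighbouring genes on chromosome 10 described at the end. Genes of the G1/S transition and DNA replication were also higher, 30 of 35 with 0 lower (31 and 0 adjusted over the list alone, camera adjusted p = 1.4e-19), for example the replication factors POLE2 (log2 fold change 0.76 ± 0.13), MCM5 (0.69 ± 0.09) and GINS2 (0.69 ± 0.07). Of the p53 targets 19 of 26 were higher and 2 lower (camera adjusted p = 6.39e-10), with BTG2 at 127 ± 0.300 against 68.1 ± 2.17 CPM.

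The output of the ERK pathway was lower in MET-D14Ex cells at 0 h. Of 22 measured genes, 15 were lower and 1 higher (camera adjusted p = 1.83e-14). DUSP6, the phosphatase that acts on ERK, stood at 28.7 ± 1.40 against 56.7 ± 0.991 CPM, DUSP4 at 136 ± 1.90 against 261 ± 6.44 CPM and the feedback inhibitor SPRY4 at 4.62 ± 0.318 against 8.87 ± 0.213 CPM. ETV5 (log2 fold change 0.03 ± 0.06) and SPRED2 (-0.10 ± 0.06) did not pass the test. NF-kB and cytokine genes were lower too, 20 of 26 with 1 higher (20 and 2 adjusted over the list alone, camera adjusted p = 1.7e-16), led by the cytokine IL6 at 8.57 ± 0.936 against 43.3 ± 6.06 CPM. The chemokine CCL20 (log2 fold change -2.09 ± 0.11), another member, lies in a run of lower genes on chromosome 2 described below. Genes of mucins and secretory cells fell short of wild type in 12 of 20 members and exceeded it in 3 (13 and 3 adjusted over the list alone, camera adjusted p = 1.61e-07). The gel-forming mucins MUC5AC (-1.90 ± 0.14) and MUC5B (-1.92 ± 0.14), neighbours on chromosome 11, were among them. Of the plasminogen system and other matrix proteases 12 of 22 were lower and 1 higher (15 and 1 adjusted over the list alone, camera adjusted p = 2.09e-08), including the plasminogen activator PLAT at 27.7 ± 3.07 against 93.5 ± 11.5 CPM. Of 6 fibroblast marker genes 4 were lower and 1 higher, the lower ones including FAP at 14.1 ± 0.457 against 30.4 ± 0.350 CPM (camera adjusted p = 0.0554 for that list with an estimated correlation).

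Several genes were close to all or none between the genotypes at 0 h. The glucose transporter SLC2A3 stood at 10.4 ± 0.192 CPM in MET-D14Ex and 0.0659 ± 0.0756 CPM in wild type cells, the axon guidance receptor ROBO1 at 44.5 ± 3.39 against 0.657 ± 0.251 CPM, and the inflammasome gene NLRP2 at 34.2 ± 1.48 against 1.03 ± 0.324 CPM. The other genes with the largest increases were VAV1 (log2 fold change 4.66 ± 0.23), PCSK1N (3.89 ± 0.17) and AUTS2 (3.88 ± 0.17). The largest decreases were those of SELENBP1 (-7.19 ± 0.30), PNMA2 (-6.43 ± 0.31), DMBT1 (-4.72 ± 0.13), ADGRL2 (-4.70 ± 0.16), the cadherin CDH11 (-4.48 ± 0.18) and SPOCK2 (-3.25 ± 0.15). Genes under 10 CPM in both groups are outside this ranking, such as COL6A1 (-11.07, with 0 CPM in MET-D14Ex cells). Without wild type 0 h replicate 1 the value for SLC2A3 was 8.54, and without MET-D14Ex 0 h replicate 1 that for PNMA2 was -7.14. In all, 99 genes with a mean of at least 1 CPM in some group were called changed and at least 4-fold apart in the same direction at 0, 6 and 24 h. Of these, 45 were higher and 54 lower in MET-D14Ex cells. This count was chosen after the values were seen, and a gene not reported here was left out of it. At 0 h, 2444 genes were higher and 2342 lower in MET-D14Ex cells, of which 321 and 471 at least 2-fold. With a filter of at least 5 CPM in 3 libraries, the count at 2-fold was 259.

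Neighbouring genes on the long arm of chromosome 2 were lower together. A scan of protein-coding genes along the autosomes, added after the values were seen and run on the 0 h libraries, marked 22 genes from AP1S3 to NCL (chromosome 2, 223751686 to 231483641, GRCh38). Of these, 21 were lower and 1 higher at 0 h, and 22 were lower at 6 h and at 24 h. Their median log2 difference was -0.96 at 0 h, -0.92 at 6 h and -0.83 at 24 h, which are 0.513, 0.527 and 0.562 of the wild type level. The 40 flanking genes had medians of 0.00 at 0 h, 0.05 at 6 h and 0.11 at 24 h. The run holds CUL3, a ubiquitin ligase subunit that works with KEAP1 in the breakdown of NRF2, at 48.6 ± 2.22 against 85.1 ± 0.555 CPM at 0 h. It also holds the insulin receptor substrate IRS1 (29.7 ± 0.826 against 77.0 ± 4.99 CPM), the protease inhibitor SERPINE2 and the nucleolar protein NCL. These genes were named after their values were seen.

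**Figure D2:**
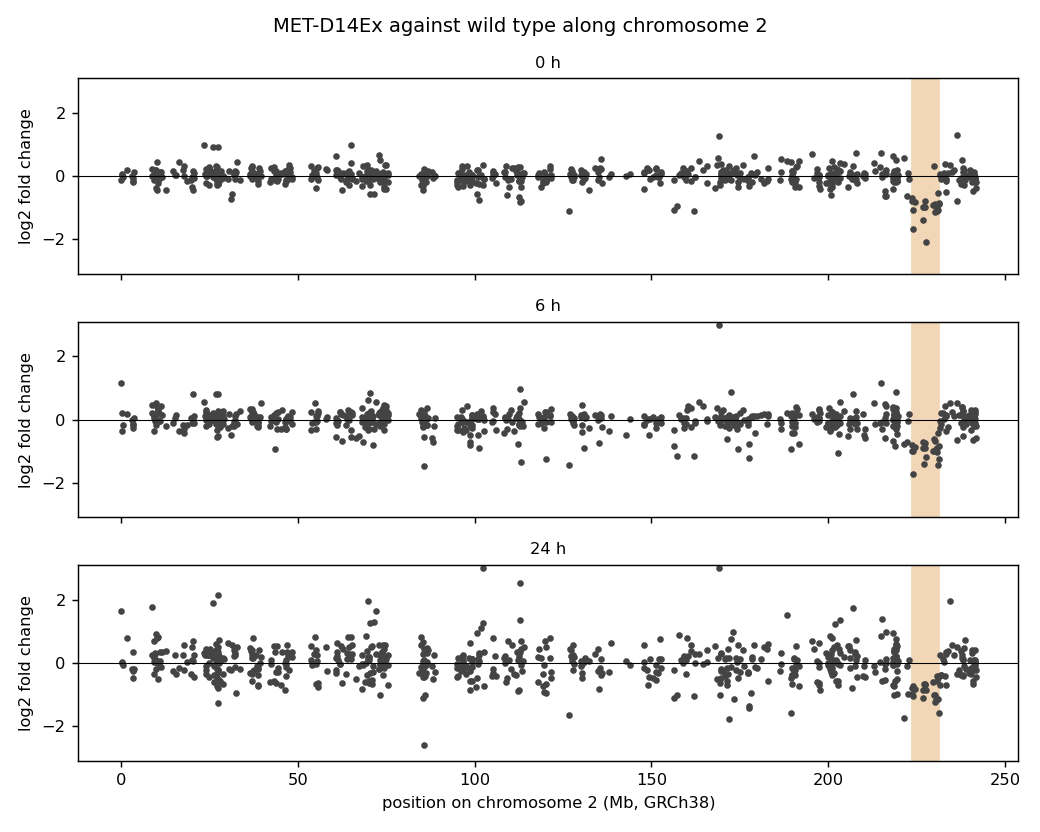
Log2 fold change of MET-D14Ex against wild type (y axis, values beyond 3 drawn at 3) for protein-coding genes with a mean of at least 5 CPM along chromosome 2 (x axis, Mb, GRCh38), at 0, 6 and 24 h from top to bottom. Points are genes and the shaded band spans the 22 genes from AP1S3 to NCL, whose median was -0.96 at 0 h.

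In wild type cells, 6 h of HGF raised genes of DNA replication, the actin cytoskeleton and the ERK pathway. All 35 measured genes of the G1/S transition and DNA replication rose (camera adjusted p = 3.63e-45), with MCM10 at 86.5 ± 4.70 against 32.9 ± 1.37 CPM and POLE2 at 15.9 ± 1.36 against 5.93 ± 1.24 CPM. Actin cytoskeleton genes and targets of the transcription factor SRF rose in 26 of 31 cases with 0 falling (camera adjusted p = 9.21e-21), such as TPM4, a tropomyosin (log2 fold change 1.13 ± 0.05), and the myosin light chain MYL9 (1.25 ± 0.07). Of the ERK output genes 18 of 22 rose and 2 fell (camera adjusted p = 8.75e-19). DUSP6 reached 130 ± 3.19 CPM from 56.7 ± 0.991 CPM, SPRY4 25.8 ± 0.736 CPM from 8.87 ± 0.213 CPM, and the AP-1 subunit FOSL1 169 ± 21.1 CPM from 55.1 ± 5.37 CPM, whereas the ephrin receptor EPHA4 fell (-1.49 ± 0.12).

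Over the same 6 h NRF2 targets and genes of FOXO and growth factor withdrawal fell in wild type cells. For NRF2 targets the counts were 18 of 25 lower and 0 higher (19 and 0 adjusted over the list alone, camera adjusted p = 2.15e-14), with the aldehyde dehydrogenase ALDH3A1 at 37.7 ± 5.10 against 171 ± 4.36 CPM. For FOXO and growth factor withdrawal they were 20 of 26 lower and 3 higher (camera adjusted p = 1.67e-10), with PIK3IP1, an inhibitor of PI3 kinase, at 4.55 ± 0.449 against 13.9 ± 0.718 CPM. Interferon-stimulated genes were lower in 29 of 36 cases and higher in 2 (camera adjusted p = 2.89e-08). That call was lost with an estimated correlation (adjusted p = 0.253). The largest increases were in IL1RL1 (log2 fold change 4.52 ± 0.14), ESM1 (4.24 ± 0.22), the interstitial collagenase MMP1 (4.10 ± 0.13), IL24 (3.65 ± 0.14), the keratin KRT6A (3.41 ± 0.10) and the actin-bundling protein LCP1 (2.77 ± 0.10). KRT6A has copies of similar sequence, and LCP1 is one of 4 blood cell markers. The largest decreases were in ATOH8 (-5.01 ± 0.21), TRIM55 (-3.26 ± 0.12), IL6 (-2.56 ± 0.12), HCAR2 (-2.39 ± 0.09), AMOT (-2.19 ± 0.12) and ALDH3A1 (-2.18 ± 0.07). Altogether 3735 genes rose and 3616 fell, 375 and 812 of them at least 2-fold. The count at 2-fold was 493 with a filter of at least 5 CPM in 3 libraries.

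After 24 h in wild type cells, glycolysis, mitosis and sterol synthesis genes were higher than at 0 h while replication, ribosome biogenesis and NRF2 target genes were lower. Of the NRF2 targets 21 of 25 were lower and 1 higher (camera adjusted p = 5.81e-41), with the cystine transporter SLC7A11 at 9.06 ± 0.755 against 93.8 ± 13.0 CPM and ALDH3A1 at 19.3 ± 1.93 against 171 ± 4.36 CPM. Ribosome biogenesis and MYC targets were lower in 28 of 30 cases and higher in 1 (camera adjusted p = 3.53e-32), including ODC1, the first enzyme of polyamine synthesis (log2 fold change -1.75 ± 0.07), and the ribosome assembly factor RRP12 (-1.43 ± 0.06). G1/S and replication genes were lower in 30 of 35 cases and higher in 1 (camera adjusted p = 1e-21), with CDC25A, a phosphatase that activates CDK2, at 13.0 ± 0.404 against 39.96 ± 2.42 CPM. All 34 G2/M and mitosis genes were higher, such as the topoisomerase TOP2A at 489 ± 9.96 against 231 ± 16.4 CPM (camera adjusted p = 8.01e-19), a call lost with an estimated correlation (adjusted p = 0.0575).

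The sterol pathway was higher in 23 of 24 genes with 0 lower at 24 h in wild type cells (camera adjusted p = 1.89e-22). Glycolysis and hypoxia genes were higher in 21 of 30 cases and lower in 4 (camera adjusted p = 1.93e-18), with carbonic anhydrase CA9 at 94.5 ± 9.04 against 13.9 ± 1.43 CPM and the aldolase ALDOC at 53.04 ± 3.80 against 9.97 ± 0.589 CPM. FOXO and growth factor withdrawal genes were higher in 24 of 26 cases and lower in 1 (camera adjusted p = 4.34e-18), with PIK3IP1 at 50.6 ± 1.68 against 13.9 ± 0.718 CPM. The largest increases were in the long noncoding RNA MIR210HG (log2 fold change 2.95 ± 0.15), EGLN3 (2.86 ± 0.11), CA9 (2.77 ± 0.09), TNFSF9 (2.56 ± 0.14), ALDOC (2.41 ± 0.09) and NRN1 (2.40 ± 0.11). The largest decreases were in GPX2 (-3.76 ± 0.17), SLC7A11 (-3.37 ± 0.17), ALDH3A1 (-3.15 ± 0.07), SERPINB2 (-2.74 ± 0.19), AKR1C2 (-2.58 ± 0.06) and NQO1 (-2.44 ± 0.05). AKR1C2 has near-identical copies in the genome. The ERK output list, with 13 of 22 genes lower and 5 higher, was not called at 24 h (camera adjusted p = 0.0589). It was called as lower without wild type 0 h replicate 1 (camera adjusted p = 0.0326) or replicate 3 (0.0436), but not with an estimated correlation (adjusted p = 0.5996). SPRY4 stood at 6.66 ± 0.686 CPM, lower than at 0 h (-0.41 ± 0.10). Of 13 mitochondrially encoded genes, a list of RNA quality, 9 were higher and 0 lower (10 and 0 adjusted over the list alone, camera adjusted p = 0.00721), a call lost with an estimated correlation (adjusted p = 0.60003). In total 3886 genes rose and 4491 fell, 734 and 472 at least 2-fold. With a filter of at least 5 CPM in 3 libraries, the count at 2-fold was 507.

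In MET-D14Ex cells, 6 h of HGF raised actin, ERK output and glycolysis genes. Actin and SRF target genes rose in 28 of 31 cases with 0 falling (camera adjusted p = 7.42e-36), with ACTB, cytoplasmic actin, at 14387 ± 281 against 4644 ± 112 CPM and the smooth muscle protein TAGLN at 26.1 ± 0.141 against 1.95 ± 0.512 CPM. ERK output genes rose in 20 of 22 cases and 1 fell (camera adjusted p = 3.52e-34), with FOSL1 at 325 ± 5.66 against 44.6 ± 0.191 CPM, SPRY4 at 49.0 ± 2.65 against 4.62 ± 0.318 CPM and the phosphatase DUSP1 at 172 ± 1.54 against 20.8 ± 1.35 CPM. Glycolysis and hypoxia genes rose in 25 of 30 cases and 1 fell (26 and 1 adjusted over the list alone, camera adjusted p = 3.37e-17), led by the angiogenic factor VEGFA at 624 ± 9.56 against 98.2 ± 1.47 CPM. FOXO and growth factor withdrawal genes fell in 21 of 26 cases and rose in 3 (camera adjusted p = 1.47e-14), such as KLHL24 (log2 fold change -2.18 ± 0.12) and PIK3IP1 (-2.52 ± 0.09).

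The neutrophil chemokines CXCL3 and CXCL2 rose in MET-D14Ex cells at 6 h, to 204 ± 9.93 CPM from 13.1 ± 0.602 CPM and to 221 ± 3.09 CPM from 26.4 ± 1.62 CPM. The NF-kB and cytokine list went both ways, with 12 of 26 genes rising and 11 falling (camera adjusted p = 1.96e-05 towards higher, 0.0298 with an estimated correlation). The largest increases at 6 h were in ESM1 (log2 fold change 6.91 ± 0.24), MMP1 (5.67 ± 0.13), KRT6A (5.17 ± 0.10), STC1 (4.50 ± 0.14), IL24 (4.50 ± 0.14) and IL1RL1 (4.28 ± 0.13). The largest decreases were in ATOH8 (-6.71 ± 0.25), IP6K3 (-5.76 ± 0.27), TRIM55 (-4.22 ± 0.13), AMOT (-3.84 ± 0.15), the muscle atrophy ubiquitin ligase FBXO32 (-3.34 ± 0.08) and SLC40A1 (-3.12 ± 0.15). Leaving out MET-D14Ex 6 h replicate 2 gave -7.30 for ATOH8. LCP1, the blood cell marker that rose in wild type cells, also stood higher here than in wild type at 6 h, at 113 ± 1.86 against 30.98 ± 2.49 CPM. Of the 4 blood cell markers 3 rose and 1 fell over the 6 h (camera adjusted p = 0.00443, adjusted p = 0.0914 with an estimated correlation). Altogether 4500 genes rose and 4885 fell, 657 and 1485 at least 2-fold. The count at 2-fold was 948 with a filter of at least 5 CPM in 3 libraries.

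At 24 h in MET-D14Ex cells, matrix metalloproteinases, integrins, ERK output and glycolysis genes were higher than at 0 h. MMP1 stood at 2827 ± 490 CPM against 9.31 ± 1.42 CPM and the stromelysin MMP10 at 462 ± 89.5 CPM against 0.207 ± 0.0942 CPM. Metalloproteinases and their inhibitors rose in 10 of 17 cases and fell in 2 (camera adjusted p = 4.18e-07). Near the floor, MMP3 rose to 0.389 ± 0.0730 CPM from 0 and MMP9 to 0.389 ± 0.0574 CPM from 0.0331 ± 0.0378 CPM, whereas MMP13 fell (log2 fold change -2.69 ± 0.16). Integrin and focal adhesion genes rose in 21 of 26 cases and fell in 3 (camera adjusted p = 6.54e-10), with the fibronectin receptor subunit ITGA5 at 241 ± 17.7 against 32.1 ± 2.57 CPM and ITGB4 at 2084 ± 108 against 658 ± 43.4 CPM. ERK output genes were higher in 20 of 22 cases and lower in 1 (camera adjusted p = 1.21e-19), among them SPRY4 at 31.7 ± 5.45 CPM and DUSP6 at 136 ± 10.4 CPM, while the cyclin CCND1 did not pass the test (0.06 ± 0.05), although it did with DESeq2 (0.11).

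Epithelial genes rose in MET-D14Ex cells at 24 h alongside some mesenchymal ones. Of the epithelial junction genes 28 of 33 rose and 3 fell (29 and 3 adjusted over the list alone, camera adjusted p = 1.37e-09), with CDH1, E-cadherin, at 635 ± 35.9 against 301 ± 3.21 CPM. Mesenchymal and EMT genes rose in 13 of 17 cases and fell in 4 (camera adjusted p = 0.00824), a call lost with an estimated correlation (adjusted p = 0.113). Their member CDH2, N-cadherin, fell (log2 fold change -3.50 ± 0.16), and VIM, vimentin, rose near the floor, to 0.345 ± 0.0769 CPM from 0.0581 ± 0.0520 CPM. Ribosome biogenesis and MYC targets fell in 29 of 30 cases with 0 rising (camera adjusted p = 4.87e-31). G1/S and replication genes fell in 32 of 35 with 1 rising (camera adjusted p = 3.73e-28), such as MCM6 at 41.2 ± 1.27 against 179 ± 13.2 CPM. Glycolysis and hypoxia genes rose in 26 of 30 cases and fell in 2 (camera adjusted p = 1.91e-22), with ENO2, a neuronal enolase, at 120 ± 8.34 against 11.5 ± 0.377 CPM. Besides MMP10 and MMP1, the largest increases were in the platelet chemokine PPBP (8.0 ± 0.22), CASP14 (6.68 ± 0.22), IL24 (5.96 ± 0.14) and DHRS9 (5.90 ± 0.26). The largest decreases were in ALDH3A1 (-5.33 ± 0.08), SLC7A11 (-3.39 ± 0.16), ATOH8 (-3.34 ± 0.17), CDCA7 (-3.23 ± 0.09), VPS9D1-AS1 (-3.14 ± 0.14) and MXRA5 (-3.08 ± 0.12). Altogether 5076 genes rose and 5846 fell, 1554 and 1825 at least 2-fold. With a filter of at least 5 CPM in 3 libraries, the count at 2-fold was 1814.

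**Figure D3:**
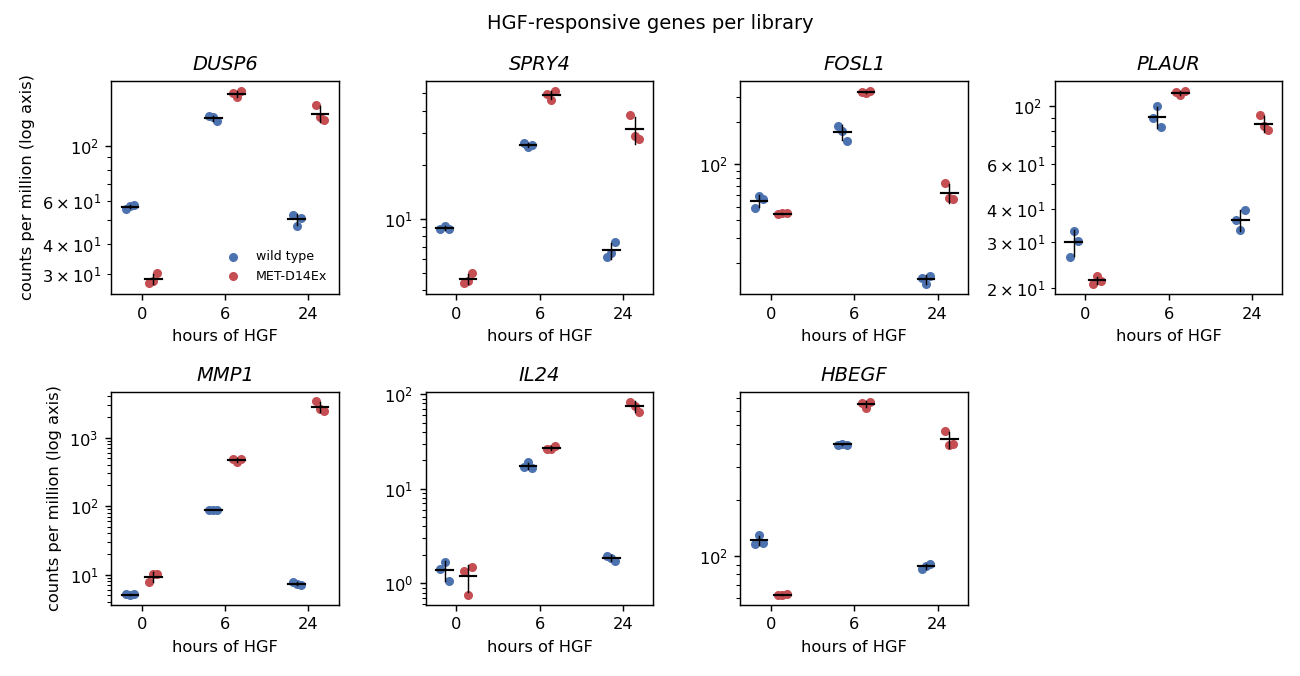
Levels of 7 genes in CPM (y axis, log scale) in each of the 18 libraries by hours of HGF (x axis). Points are libraries, horizontal bars group means and vertical bars 1 SD. SPRY4 returned to 6.66 CPM at 24 h in wild type and stood at 31.7 CPM in MET-D14Ex cells, and MMP1 at 7.36 and 2827 CPM.

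At 6 h of HGF, MET-D14Ex cells had more transcripts of actin and NRF2 target genes than wild type cells. Actin and SRF target genes were higher in 25 of 31 cases and lower in 1 (26 and 1 adjusted over the list alone, camera adjusted p = 2.94e-17), such as MYL9 at 133 ± 1.81 against 50.4 ± 3.43 CPM and CNN3 at 232 ± 6.07 against 117 ± 0.797 CPM. NRF2 targets were higher in 19 of 25 cases and lower in 2 (20 and 2 adjusted over the list alone, camera adjusted p = 8.65e-12), including the glutathione peroxidase GPX2 at 11.8 ± 1.54 against 5.08 ± 0.586 CPM. FOXO and growth factor withdrawal genes were lower in 20 of 26 cases and higher in 4 (camera adjusted p = 1.24e-05), with TXNIP, an inhibitor of glucose uptake, at 120 ± 5.23 against 269 ± 13.7 CPM. ERK output genes were higher in 10 of 22 cases and lower in 3 (camera adjusted p = 0.0039), a call lost with an estimated correlation (adjusted p = 0.342). The EGFR ligand AREG stood at 168 ± 1.28 against 100 ± 8.39 CPM. Of the 4 blood cell markers 3 were higher and 1 lower (camera adjusted p = 0.00331, adjusted p = 0.112 with an estimated correlation). Of the 6 fibroblast markers 3 were lower and 1 higher (4 and 2 adjusted over the list alone, camera adjusted p = 0.0394, adjusted p = 0.220 with an estimated correlation). At this time the largest differences were again in SLC2A3 (log2 fold change 10.25 ± 0.22), NLRP2 (6.04 ± 0.15), ROBO1 (5.69 ± 0.19) and VAV1 (5.07 ± 0.24). Lower genes with large differences were ADGRL2 (-6.21 ± 0.19), PNMA2 (-5.32 ± 0.23) and ARMCX2 (-3.88 ± 0.13). Leaving out wild type 6 h replicate 2 gave 11.11 for SLC2A3, and leaving out wild type 6 h replicate 1 gave 5.87 for VAV1. In all 2951 genes were higher and 3158 lower, 305 and 659 at least 2-fold. The count at 2-fold was 326 with a filter of at least 5 CPM in 3 libraries.

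At 24 h of HGF, ERK output, TGF-beta target, integrin and EGFR ligand genes were higher in MET-D14Ex than in wild type cells. ERK output genes were higher in 20 of 22 cases and lower in 2 (camera adjusted p = 1.32e-21, median log2 fold change 1.13), with PHLDA1 at 1244 ± 66.2 against 297 ± 11.9 CPM and FOSL1 at 62.8 ± 9.62 against 15.3 ± 1.05 CPM. The urokinase receptor PLAUR, of the matrix protease list, stood at 85.4 ± 6.06 against 36.5 ± 3.37 CPM. TGF-beta and SMAD targets were higher in 17 of 20 cases and lower in 3 (camera adjusted p = 7.64e-11), with the activin subunit INHBA at 238 ± 39.9 against 6.44 ± 0.473 CPM. Integrins and focal adhesion genes were higher in 21 of 26 cases and lower in 5 (camera adjusted p = 4.84e-07), with ITGA5 at 241 ± 17.7 against 45.4 ± 2.07 CPM. Of the EGFR family and its ligands 11 of 14 were higher and 1 lower (camera adjusted p = 3.86e-06), with HBEGF at 421 ± 42.1 against 88.0 ± 2.33 CPM, while EGFR itself did not pass the test (-0.01 ± 0.05).

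Cytokine genes went in both directions at 24 h. The list of NF-kB and cytokine genes held 14 of 26 higher and 5 lower members (camera adjusted p = 3.16e-06), with IL1B at 476 ± 45.5 against 82.4 ± 2.86 CPM and IL6 at 2.07 ± 0.139 against 8.94 ± 1.25 CPM. Ribosome biogenesis and MYC targets were lower in 27 of 30 cases and higher in 1 (camera adjusted p = 1.66e-13), including UTP20 (log2 fold change -1.43 ± 0.08) and NCL (-1.59 ± 0.05), the latter in the run of lower genes on chromosome 2. NRF2 targets were higher in 20 of 25 cases and lower in 1 (camera adjusted p = 4.05e-07), the lower one being ALDH3A1 (-1.79 ± 0.09). Of the 6 fibroblast markers 5 were lower (6 adjusted over the list alone), with FAP at 8.95 ± 0.798 against 18.6 ± 0.625 CPM (camera adjusted p = 0.136 with an estimated correlation and 0.0595 without MET-D14Ex 24 h replicate 1). Of the 4 blood cell markers 2 were higher and 0 lower (camera adjusted p = 0.0329, adjusted p = 0.160 with an estimated correlation). Of 11 nuclear long noncoding RNAs, a list of RNA quality, 7 were lower and 0 higher (camera adjusted p = 0.0318, adjusted p = 0.160 with an estimated correlation). The largest differences were in MMP10 (9.53 ± 0.21), SLC2A3 (9.43 ± 0.19), MMP1 (8.59 ± 0.14), IGFN1 (6.89 ± 0.51), ROBO1 (6.09 ± 0.19) and PPBP (5.93 ± 0.18). Among lower genes they were in COL6A1 (-7.02 ± 0.30), ADGRL2 (-6.57 ± 0.20), SELENBP1 (-6.19 ± 0.28), CKB (-4.61 ± 0.20), ARMCX2 (-4.11 ± 0.13) and CPA4 (-3.76 ± 0.16). IGFN1 varied widely between the MET-D14Ex libraries, at 36.4 ± 20.6 CPM, and was near the floor in wild type, at 0.303 ± 0.135 CPM. Leaving out MET-D14Ex 24 h replicate 2 gave -8.49 for COL6A1 and -7.94 for SELENBP1, and leaving out wild type 24 h replicate 3 gave 6.88 for ROBO1. In all 4537 genes were higher and 4954 lower, 817 and 1355 at least 2-fold. With a filter of at least 5 CPM in 3 libraries, the count at 2-fold was 899.

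**Figure D4:**
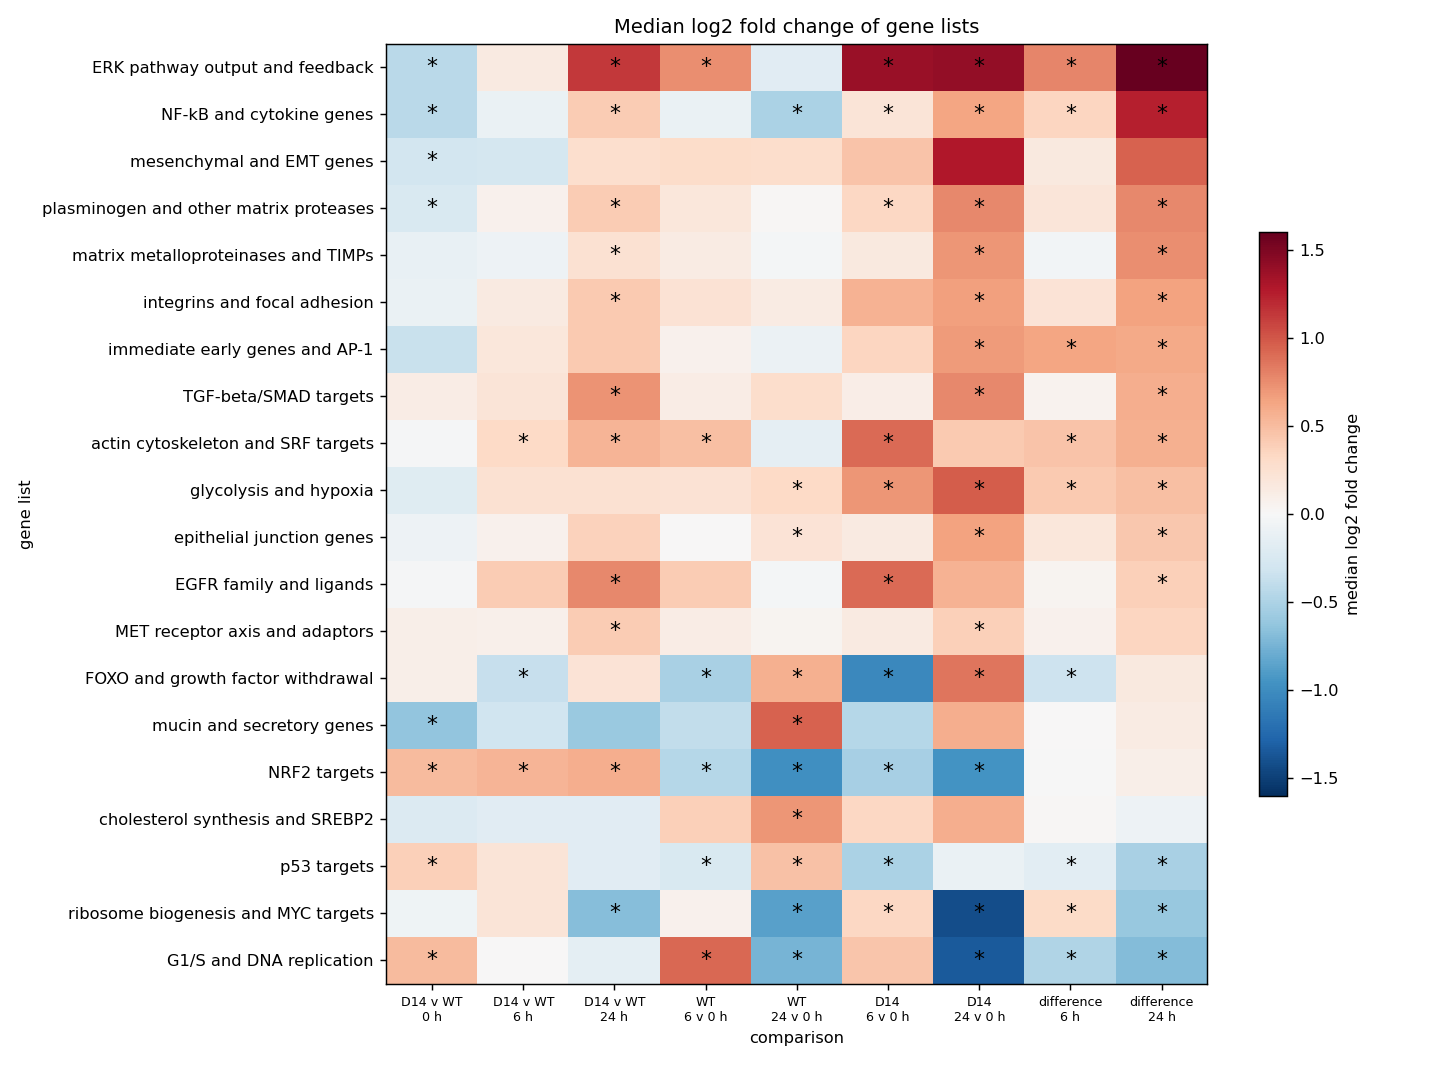
Median log2 fold change (colour) of 20 gene lists (y axis) in the 9 comparisons (x axis; WT, wild type; D14, MET-D14Ex; v, against; difference, HGF response of MET-D14Ex minus that of wild type). Stars mark the 85 cells that camera called both with the preset and with an estimated correlation. The ERK output list was negative before HGF (-0.43) and positive at 24 h (1.13) in MET-D14Ex against wild type.

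The HGF response itself differed between the genotypes at 6 h, tested as the change in MET-D14Ex minus the change in wild type. This equals the gap between the genotypes at 6 h less their gap at 0 h. At 0 h ERK output genes were lower and G1/S and replication genes higher in MET-D14Ex cells, so that starting gap is part of their values. ERK output genes changed more towards higher levels in MET-D14Ex cells in 17 of 22 cases and less in 2 (camera adjusted p = 5.97e-28), with SPRY4 at a log2 difference of 1.87 ± 0.14, DUSP1 at 1.39 ± 0.12 and DUSP6 at 1.32 ± 0.08. Actin and SRF target genes did so in 24 of 31 cases with 0 the other way (25 and 0 adjusted over the list alone, camera adjusted p = 8.68e-25), led by TAGLN (1.59 ± 0.25). Glycolysis and hypoxia genes did so in 25 of 30 with 0 the other way (camera adjusted p = 3.18e-22), led by VEGFA (1.58 ± 0.07). G1/S and replication genes responded less in 29 of 35 cases and more in 0 (31 and 0 adjusted over the list alone, camera adjusted p = 9.78e-18), such as MCM4 (-0.63 ± 0.08), ORC1 (-0.67 ± 0.10) and CDC45 (-0.73 ± 0.16). The RNA quality list of 13 mitochondrially encoded genes was called towards a more positive response (camera adjusted p = 0.00761), with 0 of 13 past the test. That call was lost with an estimated correlation (adjusted p = 0.629), without wild type 0 h replicate 1 (camera adjusted p = 0.112) and without MET-D14Ex 6 h replicate 2 (0.154). Of the 4 blood cell markers 3 were positive and 0 negative (camera adjusted p = 0.0183, adjusted p = 0.130 with an estimated correlation). The largest positive differences were in SLC2A3 (3.02 ± 0.89), ESM1 (2.67 ± 0.42), SELENBP1 (2.11 ± 0.61), DMBT1 (2.10 ± 0.17), PTGS2, the inducible cyclooxygenase (2.07 ± 0.22), and CXCL3 (2.04 ± 0.13). The largest negative ones were in ATOH8 (-1.70 ± 0.47), AMOT (-1.66 ± 0.21), SLC1A4 (-1.56 ± 0.18), GAS1 (-1.51 ± 0.17), ADGRL2 (-1.51 ± 0.33) and ZNF488 (-1.46 ± 0.16). Levels near 0 made some of these depend on 1 library: without wild type 0 h replicate 1 the difference for SLC2A3 was 1.71 (edgeR adjusted p = 0.437), and without MET-D14Ex 6 h replicate 1 that for ATOH8 was -1.21 (edgeR adjusted p = 0.0582), while without MET-D14Ex 6 h replicate 2 it was -2.29. The difference was positive for 1751 genes and negative for 1901, at least 2-fold for 153 and 242. The count at 2-fold was 183 with a filter of at least 5 CPM in 3 libraries.

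At 24 h the difference between the responses was larger. Here too the gap at 0 h is part of the values, as for NF-kB and cytokine genes, lower then, and p53 targets, higher then. ERK output genes had a more positive response in MET-D14Ex cells in 20 of 22 cases and a more negative one in 1 (camera adjusted p = 8.44e-44, median log2 difference 1.61), with SPRY4 at 3.19 ± 0.14, PHLDA1 at 2.50 ± 0.07, DUSP6 at 2.42 ± 0.08 and FOSL1 at 2.34 ± 0.15. NF-kB and cytokine genes followed in 20 of 26 cases with 1 the other way (20 and 2 adjusted over the list alone, camera adjusted p = 2.66e-20), with CXCL3 at 3.07 ± 0.15, CXCL2 at 2.71 ± 0.09 and IL1B at 2.56 ± 0.07. Of the plasminogen system and other matrix proteases 15 of 22 were positive and 0 negative (camera adjusted p = 1.16e-14), with SERPINB2 at 3.96 ± 0.25, ADAMTS1 at 2.38 ± 0.18, ADAM8 at 2.12 ± 0.09 and the urokinase PLAU at 1.76 ± 0.09. Of the p53 targets 19 of 26 were negative and 1 positive (camera adjusted p = 1.1e-07), such as BTG2 (-1.34 ± 0.07). Ribosome biogenesis and MYC targets were negative in 24 of 30 cases and positive in 1 (25 and 1 adjusted over the list alone, camera adjusted p = 1.61e-10). Of the 11 nuclear long noncoding RNAs of the RNA quality list 9 were negative and 0 positive (camera adjusted p = 0.0347). That call was lost with an estimated correlation (adjusted p = 0.137) and without MET-D14Ex 24 h replicate 1 (camera adjusted p = 0.0515). The largest positive differences were in MMP10 (9.27 ± 1.25), MMP1 (7.72 ± 0.22), IL24 (5.55 ± 0.26), PPBP (5.41 ± 0.69), TMEM158 (4.92 ± 0.13) and ESM1 (4.90 ± 0.45). The largest negative ones were in ATOH8 (-2.81 ± 0.23), PLIN4 (-2.76 ± 0.18), CPA4 (-2.63 ± 0.21), MXRA5 (-2.58 ± 0.17), GAS1 (-2.35 ± 0.15) and EPHA4 (-2.31 ± 0.16). MMP10 was near the floor at 0 h in MET-D14Ex cells. Its change at 24 h in wild type (log2 fold change 1.83) lost its call without wild type 0 h replicate 1 (edgeR adjusted p = 0.0751) or replicate 3 (0.0895). The difference was positive for 3445 genes and negative for 3835, at least 2-fold for 783 and 909. With a filter of at least 5 CPM in 3 libraries, the count at 2-fold was 880.

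The genotypes shared much of the direction of their HGF responses and differed in size. At 6 h, 241 genes rose at least 2-fold in both, where independent lists would share 14.8, and 571 fell in both, where they would share 72.7. At 24 h the shared counts were 369 against 68.7 and 327 against 51.9, and 14 genes that rose and 19 that fell at least 2-fold in wild type did the opposite in MET-D14Ex cells. Among 1718 genes with an average 6 h response of at least 2-fold, the median response was larger in MET-D14Ex cells by 0.54 on the log2 scale, and 76.0% of these genes responded more there. Among 2088 such genes at 24 h the median extra was 0.79 and the share 82.6%. Each HGF library was scored by its mean response over these genes, taken from the 0 h mean of its genotype. The scores were 1.68 ± 0.0113 in MET-D14Ex and 1.22 ± 0.0233 in wild type at 6 h. At 24 h they were 1.80 ± 0.0507 and 0.997 ± 0.00749 (SD, n = 3). These SDs leave out the spread of the 0 h libraries, and the gap between the genotypes at 0 h enters the scores. An exact two-sided permutation test gave p = 0.1 at both times, which is the smallest that 3 against 3 libraries allow. Regrouped scores kept the 0 h mean of their own genotype, so the test does not cover chance in the 0 h libraries. The AP-1 gene FOSL1 and the cyclin gene CCND1 did not follow this at 24 h. FOSL1 changed by -1.85 ± 0.11 in wild type and 0.49 ± 0.10 in MET-D14Ex, and CCND1 by -1.002 ± 0.05 and, not past the test, 0.06 ± 0.05.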

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

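The tests of other groupings of the libraries were planned, and the remaining tests in this part were chosen after the results were seen. So was the choice of which differences to list. Genes had a mean of at least 1 CPM in the highest group and above 0 in every group. Lists were called by camera with both the preset and an estimated correlation.

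The results here stand out because the HGF response differed between the genotypes when the difference itself was tested. Each value is the log2 response of MET-D14Ex minus that of wild type. It holds the gap at 0 h with its sign reversed, so genes and lists that differed at 0 h are not compared from an equal start. At 6 h the difference was positive for 1751 genes and negative for 1901, and at least 2-fold for 153 and 242. Positive differences were those of CDH1 (0.20), ITGA2 (0.51), EGR1 (0.63), CCND1 (0.64), PLAUR (0.79), AREG (0.97), FOSL1 (1.25), DUSP6 (1.32), MMP1 (1.57), SPRY4 (1.87), CXCL3 (2.04), PTGS2 (2.07), DMBT1 (2.10), SELENBP1 (2.11), ESM1 (2.67) and SLC2A3 (3.02). Negative ones were those of MET (-0.38), MMP13 (-1.06), ZNF488 (-1.46), ADGRL2 (-1.51), GAS1 (-1.51), SLC1A4 (-1.56), AMOT (-1.66) and ATOH8 (-1.70). The call for CDH1 was lost when any of 6 of the 12 libraries was left out, with upper-quartile factors and with no filter beyond 1 count. That for SLC2A3 was lost without wild type 0 h replicate 1 (1.71), and that for ATOH8 without MET-D14Ex 6 h replicate 1 (-1.21). In MET-D14Ex cells SELENBP1 (0.0745 CPM at 0 h and 0.221 CPM at 6 h) and ADGRL2 (0.505 and 0.195 CPM) were near the floor. So was SLC2A3 in wild type cells (0.0659 and 0.0260 CPM). The median over a list was 0.79 for ERK output, 0.63 for immediate early genes, 0.46 for actin and SRF targets, 0.42 for glycolysis and hypoxia, 0.34 for NF-kB and cytokines and 0.30 for ribosome biogenesis. It was -0.17 for p53 targets, -0.33 for FOXO and growth factor withdrawal and -0.48 for G1/S and DNA replication.

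At 24 h the difference was positive for 3445 genes and negative for 3835, and at least 2-fold for 783 and 909. Positive differences were those of CDH1 (0.37), MET (0.69), EGR1 (0.91), ITGA2 (0.95), CCND1 (1.06), AREG (1.14), PLAUR (1.71), FOSL1 (2.34), DUSP6 (2.42), SPRY4 (3.19), ESM1 (4.90), TMEM158 (4.92), PPBP (5.41), IL24 (5.55), MMP1 (7.72) and MMP10 (9.27). Negative ones were those of MMP13 (-1.48), EPHA4 (-2.31), GAS1 (-2.35), MXRA5 (-2.58), CPA4 (-2.63), PLIN4 (-2.76) and ATOH8 (-2.81). MMP10 was near the floor at 0 h in MET-D14Ex cells. List medians were 1.61 for ERK output, 1.24 for NF-kB and cytokines, 0.77 for matrix proteases, 0.74 for metalloproteinases, 0.64 for integrins, 0.61 for immediate early genes, 0.58 for TGF-beta targets, 0.57 for actin and SRF targets, 0.48 for glycolysis and hypoxia, 0.43 for epithelial junctions and 0.38 for the EGFR family. They were -0.52 for p53 targets, -0.60 for ribosome biogenesis and -0.69 for G1/S and DNA replication.

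Other groupings of the same libraries were tested for the counts of changed genes in the 9 comparisons, and not for the shared genes or the 99 genes below. For the differences, 30 regroupings that mix genotypes within a time were used, the real one included. At 24 h the real grouping gave 7086 genes and the highest other 4853, and at 2-fold 1679 against 1284, so 1 of 30 was as large. At 6 h it gave 3841 against 1834, again 1 of 30. Regroupings that mix the genotypes carry their difference into the spread within groups or into the contrast. The real grouping was thus the largest of those drawn for these counts, which cannot exclude chance differences between cultures. For the 2-fold count at 6 h, 3 of 30 were as large, with 391 genes for the real grouping and 402 for the highest other, so chance is not excluded for that count. Between 2 groups, 3 against 3 libraries make only 10 groupings, too few for a share under 0.05. There the real grouping was the 1 of 10 with the most genes, and the highest other gave 0 in each case. The counts of the real grouping, in fits of those 6 libraries, were 4640, 6300 and 9122 for MET-D14Ex against wild type at 0, 6 and 24 h, with 713, 832 and 2022 at 2-fold. They were 7061 and 8673 for wild type at 6 and 24 h of HGF, with 1055 and 1162 at 2-fold, and 9658 and 10366 for MET-D14Ex, with 1908 and 3136 at 2-fold.

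The run of 22 lower genes on chromosome 2 was chosen on the 0 h libraries. Its median at 24 h, in other libraries, was -0.831, as a lower copy number in the MET-D14Ex cells would give, and this may be its cause. In wild type cells 24 h of HGF changed the median of the run by -0.0774, which argues against HGF signalling, and 0 of 1000 shuffles of the gene order gave a run that scored as high. DNA was not measured, and regional silencing was not tested. Whether the run came with the change in MET or with the choice of a clone cannot be read from the labels.

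The 99 genes at least 4-fold apart at all 3 times are the next pattern. For the 93 of them with neighbours in the scan, the 10 nearest genes had a median signed difference of 0.0035. This argues against copy number changes that span the neighbours of most of these 93. A gain or loss limited to the gene itself or to few neighbours would not move that median and is not excluded. Of the 99 genes 19.2% changed at least 2-fold the same way on HGF in wild type cells, against 6.85% of 13629 other genes. A 2-fold change near the floor, as for SLC2A3 in wild type (0.0659, 0.0260 and 0.0759 CPM at 0, 6 and 24 h), may not pass the test. A response of wild type cells to HGF also does not measure lasting signalling in MET-D14Ex cells. The share therefore does not decide how many of the 99 genes HGF signalling accounts for. Differences between clones and effects of the MET change may both contribute and were not tested.

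The last pattern is that 6 lists were called in the same direction at 24 h in both genotypes, with the preset and with an estimated correlation. Time in culture acting alike in both genotypes could give this. The change differed between the genotypes for glycolysis and hypoxia (camera adjusted p = 0.0264 for the difference, estimated correlation) and G1/S and DNA replication (0.0269). It also differed for epithelial junctions (0.0192) and ribosome biogenesis (0.0033). An equal log2 change with time in both genotypes cannot be the whole cause there. The gap at 0 h is part of each difference, so time in culture acting unequally, or from unequal starts, is not excluded. For NRF2 targets (0.900) and FOXO and growth factor withdrawal (0.299) the difference did not pass the test, and HGF and time in culture cannot be told apart, since no library without HGF was analysed at 24 h.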

How the results depend on the processing

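No alternative was added after the results were seen. With a filter of at least 5 CPM in 3 libraries, fewer genes were tested and the counts at 2-fold fell to 259, 326 and 899 for MET-D14Ex against wild type at 0, 6 and 24 h. They fell to 493 and 507 for wild type at 6 and 24 h of HGF, 948 and 1814 for MET-D14Ex, and 183 and 880 for the differences at 6 and 24 h. The extra response of MET-D14Ex at 6 h was 0.587 with that filter and 0.502 with no filter beyond 1 count, against 0.541. The cause was not tested. Without 1 library it lay between 0.483 and 0.607 at 6 h and between 0.736 and 0.852 at 24 h. With no size limit the genotypes shared 2907 higher and 2834 lower genes at 6 h and 2638 and 3304 at 24 h, since more genes count. The other counts stayed within 1.5 times under every alternative run, and the MET level kept its side of the threshold, and its direction where it was past it. The 24 h response moved by less than the spread between libraries, except without wild type 0 h replicate 1 or MET-D14Ex 24 h replicate 2, which gave the ends of its range.

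MMP9, near the floor, had a log2 difference of MET-D14Ex against wild type at 6 h that lay between -5.07 and 0.70 without 1 library. The lowest value came without MET-D14Ex 6 h replicate 2, where both libraries left held 0 counts, so that value is no estimate of a fold.

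In the 342 list tests, 104 of the calls made by camera with the preset correlation were lost with an estimated one, and 85 held. RLE factors lost 3, and fry in 1 direction gained 74 and lost 3. Without regard to direction, fry gained 136 and lost 1. Leaving out 1 library gained 41 and lost 34 of the tests run. RLE and upper-quartile factors moved the median of all genes by less than 0.1, the most being -0.0814.

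With the replicate number as a replicate block, 4834 genes differed at 0 h against 4786, and no count changed by over 1.5 times. Residuals of the 45 same-number pairs correlated between -0.0629 and 0.0550, and 3 of 18 libraries were closest to their own number, so the numbers do not pair the libraries. At this depth, genes with a few counts give unstable folds.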

Other observations

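The hypothesis below was formed and tested after the results were seen, on the same libraries.

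MET-D14Ex cells may hold the raised part of the early HGF response longer. Across 10740 genes, which are not independent replicates, the difference between the genotypes at 24 h correlated with the 6 h response of wild type (Pearson's r = 0.402), and these share no library. The difference at 0 h had r = 0.0148 with the change of wild type from 6 to 24 h. To see whether the response is held or only larger, genes with a mean of at least 5 CPM were chosen by a 2-fold change at 6 h in 1 genotype and measured in the other. Of those raised, 190 genes had a median log2 change of 1.76 at 6 h and 1.37 ± 0.120 at 24 h in MET-D14Ex (SD, n = 3), a kept share of 0.779, and 345 had 0.872 and -0.139 ± 0.00913 in wild type. Of those lowered, 202 had -1.71 and -0.187 ± 0.050009 in MET-D14Ex, a kept share of 0.109, and 456 had -0.887 and 0.399 ± 0.0160 in wild type. This argues against a response larger by the same factor at both times. The genotypes were measured on different gene sets, however, and the choice of genes may add to the gap between them. In MET-D14Ex raised genes were mostly held and lowered ones mostly not, and HGF and time in culture were not separated.

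A run of 6 higher genes on chromosome 9, from INPP5E to DIPK1B, had medians of 1.04, 0.92 and 1.15 at 0, 6 and 24 h, and 0 of 1000 shuffles gave a run that scored as high. A run of 3 genes on chromosome 10, from AKR1C1 to AKR1C3, was matched by 30 of 1000 shuffles. In wild type cells the median of these 3 genes changed by -1.30 at 6 h and -1.37 at 24 h of HGF.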
